A study of Oryza sativa with 27 samples.

How the data were processed

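Rice (Oryza sativa) ovaries were collected before pollination and 1, 2, 3 and 4 days after pollination (DAP) and divided into a smaller bottom part and a larger top part. Per the labels the bottom part held the embryo and the top part was mainly endosperm after pollination, and the unpollinated parts were the reference. Biotin-labelled cRNA made from total RNA of each part was hybridised to an Affymetrix rice array of 57381 probe sets, 1 sample per array. The 27 arrays fell into 10 groups: 3 arrays in each of the 5 bottom groups and in the top groups before pollination and at 4 DAP, and 2 arrays in each of the top groups at 1, 2 and 3 DAP. The labels call the arrays of a group biological replicates but do not say from which plants or panicles the samples came.

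The values used were the deposited intensity of each probe set, 1 value per probe set and array. GCOS 1.3 was used to read the arrays, per the submitters' processing notes. The summary algorithm, background step and detection calls are not given in the sources used here. From the values themselves, each array was on a linear scale and divided by its own 75th percentile, so that a value of 1 equals that percentile. The values ran from 0.01 to 286.8, and the lowest value was seen on 6 arrays, once on each. The design had assumed globally scaled signals. Since the values turned out to be relative to an upper percentile, every change below is relative to that percentile of the same array, and a change of total RNA per cell is not measured. No detection call or background level was used, so a low value is given as a value and not as presence or absence. The number of arrays limits the precision.

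Analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Values were tested as log2(value + 0.13), where the pseudocount 0.13 is the 20th percentile of all values of rice probe sets. A fold given below is on that scale and understates the change of genes with low values. Of 57258 rice probe sets, 29332 with a mean over all arrays above the median of all values (0.264) were tested, and the 123 control probe sets were not. All arrays entered 1 fit of 10 group means in limma (lmFit, then eBayes with an intensity trend), which left 17 residual degrees of freedom and a prior of 3.68, so the groups of 2 arrays borrowed the spread of the others. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The comparisons were each day against the unpollinated group of the same part, the top against the bottom part at each of the 5 stages, and the difference between the parts in the change since the unpollinated stage. Groups, tests, gene lists, the rule for naming genes and all alternatives except those named as added were fixed before the data were examined.

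Probe sets were named from a table that pairs them with genes: 22436 rice probe sets had 1 gene, 95 had several and 34727 had none there. The 17905 genes so reached were all found in a RefSeq gene table, which was used for names. Its coordinates were not used, because the build behind the array's design is not given in the sources used here. Genes are therefore identified by symbol and NCBI gene number, without positions. For a gene with several tested probe sets, the brightest stood for the gene, which gave 15275 genes. Of 2187 genes with several tested probe sets, between 0 and 41 per comparison had probe sets called in opposite directions, the most in the top part at 4 DAP, where RPL27 (LOC4327257) was the gene among those named below. Some probe sets can bind transcripts of related genes, so members of large families may share signal.

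Genes were named by rule. In the comparisons of 4 DAP with the unpollinated stage in each part and of the parts at 4 DAP, these were the 4 largest rises and 4 largest falls among called genes whose arrays did not overlap between the groups and which had an informative name. From each list with at least 3 called genes, the 2 called genes with the largest change were added. In every other comparison the 2 largest rises and 2 largest falls were named. The annotation held symbols and synonyms but no descriptions, so an informative name was read as a symbol other than a locus number, which 2112 of the 15275 genes had. For the same reason the members of the lists were taken by patterns on symbols and synonyms, written before any comparison was computed. This makes the lists shorter than the families they stand for.

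The 23 lists tested were seed storage proteins, seed allergens and inhibitors, starch synthesis, sucrose transport and cleavage, DNA replication, mitosis, core histones, cytosolic ribosomal proteins, photosynthesis, ovule and nucellus factors, Polycomb and DNA methylation, embryo patterning factors, endosperm transcription factors, auxin, gibberellin, cytokinin, cell death proteases, cell wall loosening, cellulose and callose synthesis, aquaporins, lipid transfer proteins, heat shock proteins and defence proteins. Photosynthesis stood for green ovary wall, and heat shock and defence proteins stood for stress. A pollen list had 4 genes on the array and 0 above the filter, and a list of type I MADS-box factors had 0 genes, so neither was tested. Each list was tested with camera of limma against all other genes at a preset correlation of 0.01, with adjustment over the 23 lists, and again with the correlation estimated from the residuals. Of 116 list results called over the 17 comparisons, 114 were lost with the estimated correlation.

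Simulated data were made from each probe set's mean over all arrays, plus independent normal noise with its spread within groups. They held no real group differences. The procedure was tested on them after changes had been planted. For the bottom part at 4 DAP it recovered 66% of 100 probe sets changed by 1 on the log2 scale and 88% of 100 changed by 2, with 9 of 29109 unchanged probe sets called. For the top part at 1 DAP these shares were 50% and 83%, with 5 unchanged probe sets called. For the difference between the parts at 4 DAP they were 22% and 71%, with 5 called. A shift of 0.5 planted in the ribosomal protein list for the self-test had an adjusted p of 5.12e-19 in camera, with 0 of 22 other lists called. Since the noise was independent between probe sets, this run cannot show how often lists of correlated genes are called falsely. It also used 1 spread per probe set for all groups. On the real arrays 42.9% of the variation within groups lay on 1 axis. The unchanged probe sets called above are therefore no measure of false calls in the real data.

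The alternatives were a minimum change of 2-fold, quantile normalization, shifting arrays to 1 median, pseudocounts at the 40th and 5th percentiles (0.203 and 0.0798), no filter, a filter at the 75th percentile (0.996), no intensity trend, the replicate number as a block, only the arrays of the groups compared, leaving out each array in turn, and, for lists, the mean of all probe sets of a gene. For comparisons that involve both parts, stage and replicate number together also served as a block (block by stage), which pairs the parts by number. Added after the arrays had been seen were the 18S ribosomal RNA signal as a covariate and a fit without bottom replicates 3 of 2, 3 and 4 DAP. The runs of the alternatives on lists called outside the 4 DAP comparisons were also added then.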

Results

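Transcript levels were measured in a bottom and a top part of rice ovaries, before pollination and on each of the first 4 days after pollination (DAP). Per the labels the bottom part held the embryo and the top part was mainly endosperm after pollination, and the unpollinated parts were the reference. Each group had 3 arrays, except the top part at 1, 2 and 3 DAP with 2 arrays each, and values are relative to the 75th percentile of each array. Arrays of 1 group correlated over probe sets with r between 0.863 and 0.978 (median 0.955), and no pair of arrays was identical. Arrays of different groups correlated with r between 0.7101 and 0.9765, so some were as alike as arrays of 1 group. The highest was between bottom replicates 1 of 1 and 2 DAP. Replicate 3 of the bottom part stood apart from its group at 3 and 4 DAP (root mean square log2 deviation from the group mean 0.516 and 0.484). At 2 DAP replicates 3 and 2 deviated about equally (0.367 and 0.356). Replicate 3 of 2 DAP lay with those of 3 and 4 DAP on the second principal component. These 3 are called below the arrays that stood apart. The lists that deviated most were not the same in each of the 3. The median log2 deviation of 22 heat shock protein genes from the group mean was 0.30, 0.24 and 1.35 in these arrays at 2, 3 and 4 DAP. It was -0.07, -0.95 and -0.68 for 21 cell wall loosening genes and -0.18, -1.19 and -0.33 for 5 lipid transfer protein genes. The 18S ribosomal RNA control ran from 0.127 to 33.6 and lay above 2 on 13 arrays, of which 1 was among the 6 unpollinated arrays. Its mean was 4.44 ± 7.19 (SD, n = 3) in the unpollinated bottom part and 15.4 ± 16.9 at 4 DAP, and 0.579 ± 0.21 in the unpollinated top part and 6.53 ± 10.7 at 4 DAP (SD, n = 3 each). In the top part at 3 DAP it was 24.7 ± 1.04 (SD, n = 2), so 18S signal and stage go together in that comparison.

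**Figure D1:**
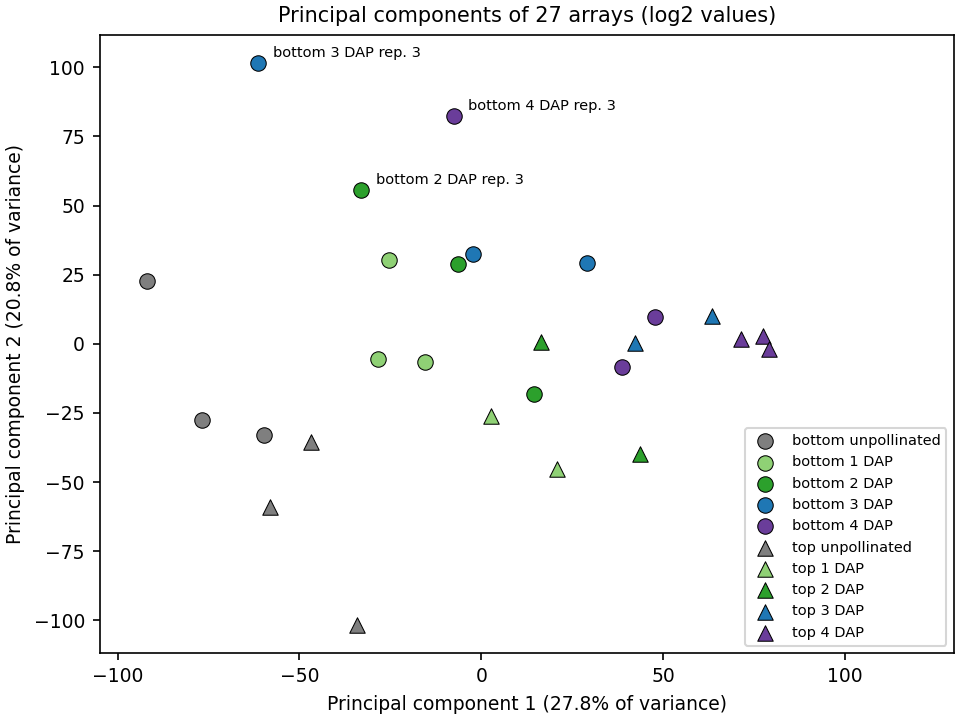
Scores of the 27 arrays on the first and second principal components of the log2 values of 29332 probe sets, with 27.8% and 20.8% of the variance on the horizontal and vertical axis; colour gives the day and shape the part. Replicate 3 of the bottom part at 2, 3 and 4 DAP lies at 55.5, 101.6 and 82.3 on the vertical axis, above all other arrays.

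What changed in the bottom part after pollination was asked by setting each day against the unpollinated bottom part. PBZ1 (LOC4352491), a pathogenesis-related protein first known as inducible by probenazole, rose 233-fold within 1 day, from 0.264 ± 0.0277 to 91.4 ± 1.37 (SD, n = 3 each, log2 change 7.86 ± 0.43 SE, adjusted p = 1.69e-10). CYP71Z7 (LOC4329726), a cytochrome P450 of phytoalexin synthesis, rose 66.3-fold at 1 DAP (log2 change 6.05 ± 0.73). OsChia1d (LOC4338720), a chitinase, fell from 114.8 ± 26.2 to 1.08 ± 0.17 at 1 DAP (log2 change -6.55 ± 0.62), and OsEXPA1 (LOC4335222), an expansin that loosens cell walls, fell 20.5-fold (log2 change -4.36 ± 0.53). PBZ1 stayed called at 2 and 3 DAP (log2 changes 7.68 and 7.33, each ± 0.43) and OsChia1d stayed lower (-7.97 and -8.49, each ± 0.62). OsAsp1 (LOC4349962), an aspartic protease, rose 36.8-fold at 2 DAP and 37.7-fold at 3 DAP. OsEXPB9 (LOC4349301), a beta-expansin, fell 22.3-fold at 2 DAP and OsRAA1 (LOC4326229), first described in root development, fell at 3 DAP (log2 change -4.81 ± 0.57).

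On the first day mitosis genes and core histones had the lowest camera adjusted p of the lists in the bottom part. Brackets after a list give first the number of genes called when adjusted over the list alone and then the camera adjusted p. All 6 core histones rose at 1 DAP (6 adjusted over the list alone, camera adjusted p = 2.09e-08, median log2 change 1.76), and H2B.11 (LOC4327384) changed by 1.70. Of 14 mitosis genes 11 rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 4.56e-11). Among them were the mitotic cyclin genes CycB2;2 (LOC4342121) at 3.79 and CYCB1-1 (LOC4327547) at 3.01. Of 26 DNA replication genes 13 rose (16 adjusted over the list alone, camera adjusted p = 7.05e-07), and of 23 cytosolic ribosomal proteins 13 rose (16 alone, 2.61e-07). With an estimated correlation these calls were lost, with adjusted p = 0.0718 for histones, adjusted p = 0.0793 for mitosis, adjusted p = 0.445 for DNA replication and adjusted p = 0.357 for ribosomal proteins. The other lists called at 1 DAP were photosynthesis, with 2 of 8 genes lower (4 adjusted over the list alone, camera adjusted p = 0.0143), gibberellin, with 5 of 9 higher and 1 lower (6 and 1 alone, 0.00398), cell death proteases, with 2 of 3 higher (3 alone, 0.00593), and defence proteins, with 6 of 12 higher and 2 lower (6 and 2 alone, 0.0146). These were lost too, with adjusted p = 0.507, adjusted p = 0.0684, adjusted p = 0.0793 and adjusted p = 0.357 with an estimated correlation. OsCPS2 (LOC9266189), the gibberellin list member with a log2 change of 5.38, is known for the synthesis of phytoalexins from the same precursor.

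At 2 and 3 DAP the bottom part had 5 and 7 lists called, none of which held with an estimated correlation (lowest adjusted p = 0.152 and 0.245). Mitosis genes were higher at both days, with 10 of 14 rising at 2 DAP (12 adjusted over the list alone, camera adjusted p = 3.43e-08) and 7 at 3 DAP (9 alone, 0.00383). Starch synthesis was first called at 3 DAP, where 5 of 9 genes rose (6 adjusted over the list alone, camera adjusted p = 0.0172). Photosynthesis, lower at 1 DAP, was higher at 3 DAP with 6 of 8 rising and 1 falling (7 and 1 alone, 0.0172). Replicate 3 of 3 DAP, which stood apart, had median log2 deviations of -0.73 on the starch list and -0.81 on the photosynthesis list, and both lists stayed called in camera without it. Over all probe sets, 2287 rose and 1644 fell at 1 DAP, 2287 and 1890 at 2 DAP, and 2445 and 2247 at 3 DAP, of 29332 tested with limma. The count at 1 DAP came to 2590 without unpollinated replicate 3 and 2604 without 1 DAP replicate 3, against 3931, and that at 2 DAP to 2747 without 2 DAP replicate 1, against 4177. With no filter, falls outnumbered rises at 2 DAP (1940 higher, 1969 lower) and 3 DAP (1972 and 2246), and at 3 DAP they also did with only the arrays compared (622 and 682) and without unpollinated replicate 2 (1678 and 1725). The starch call at 3 DAP was lost without unpollinated replicate 3 or 3 DAP replicate 1 (adjusted p up to 0.0819), and so was the photosynthesis call at 1 DAP without unpollinated replicate 2 or 1 DAP replicate 1 (up to 0.118). The photosynthesis call at 3 DAP was lost without unpollinated replicate 1 or 3 DAP replicate 1 or 2 (up to 0.0883). At 1 DAP the defence call was lost without unpollinated replicate 1 (0.0571) and that of cell death proteases with no filter (0.0688).

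**Figure D2:**
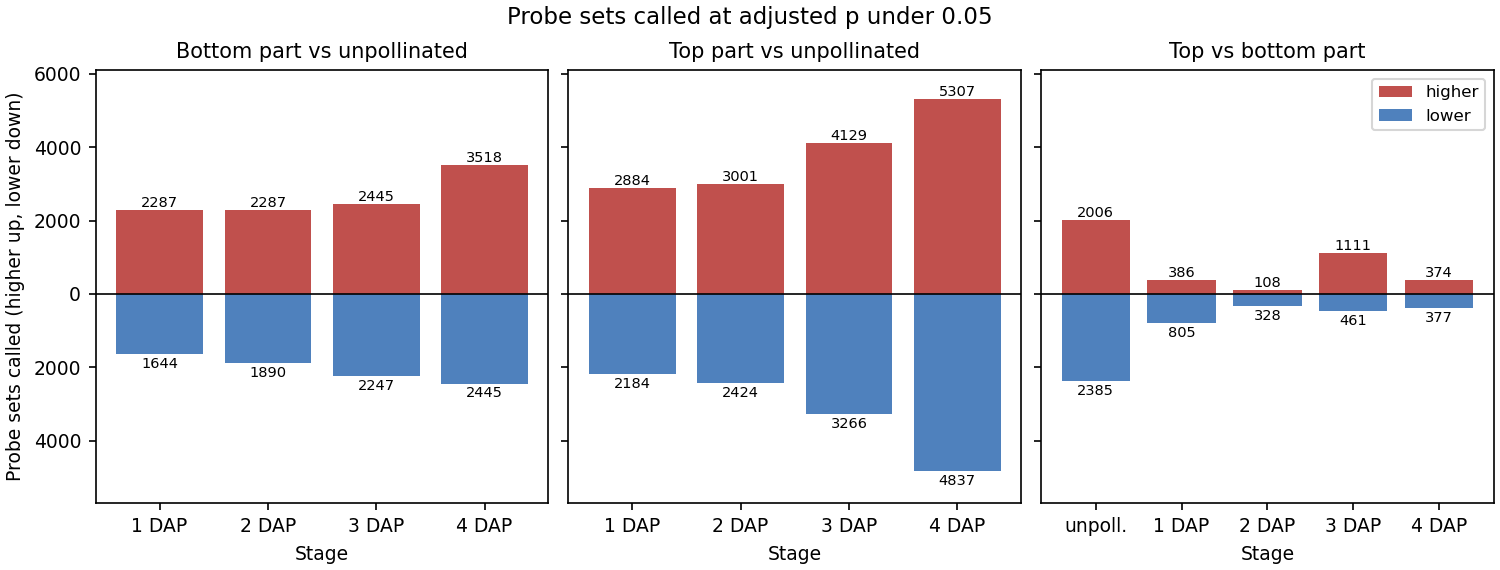
Number of probe sets called higher (up) and lower (down) of 29332 tested, for each day against the unpollinated group of the same part and for the top against the bottom part at each stage. The counts run up to 5307 higher and 4837 lower in the top part at 4 DAP, while 374 were higher and 377 lower in the top than in the bottom part on that day.

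At 4 DAP the largest rises among the genes named in the bottom part included single genes of starch and sucrose metabolism. Wx (LOC4340018), the granule-bound starch synthase that makes amylose, rose 42.8-fold, from 0.218 ± 0.101 to 14.6 ± 3.15 (SD, n = 3 each, log2 change 5.42 ± 0.70 SE, adjusted p = 9.73e-06), and OsSUS3 (LOC4343910), a sucrose synthase, rose 40.1-fold (log2 change 5.32 ± 0.50 SE, adjusted p = 1.20e-07). PBZ1 stood at 73.5 ± 19.3 (183-fold, log2 change 7.52 ± 0.43) and OsAsp1 at 58.7 ± 13.2 against 1.39 ± 0.43 (39.3-fold, log2 change 5.30 ± 0.30). OsChia1d fell 341-fold to 0.201 ± 0.0279 (log2 change -8.41 ± 0.62, adjusted p = 4.47e-09). OsRAA1, OsEXPB9 and OsNIP2;1 (LOC4330713), a silicon transporter, fell 40.1-fold, 24.5-fold and 11.5-fold.

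Of the 23 lists, 7 were called in the bottom part at 4 DAP, and all 7 calls were lost with an estimated correlation. Starch synthesis had 6 of 9 genes higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 9.12e-04, adjusted p = 0.334 with an estimated correlation). Besides Wx, AGPS2 (LOC4345339), a small subunit of ADP-glucose pyrophosphorylase, changed by 2.81 ± 0.35 and SSII-3 (LOC4340567), a soluble starch synthase, by 2.67 ± 0.49. Cell death proteases had all 3 genes higher (3 alone, 5.77e-04, adjusted p = 0.0728 with an estimated correlation). The aspartic protease AP25 (LOC4331874) changed by 2.58 ± 0.52 and the vacuolar processing enzyme OsVPE1 (LOC4336523) by 1.23 ± 0.19. Of 14 mitosis genes 9 rose (10 adjusted over the list alone, 5.77e-04, adjusted p = 0.409 with an estimated correlation), CycB2;2 by 2.70 ± 0.42 and CYCB1-1 by 1.71 ± 0.34. Of 6 core histones 4 rose (4 alone, 0.0129, adjusted p = 0.422 with an estimated correlation), H2B.11 by 1.19 ± 0.17 and OsH2B (LOC4324500) by 0.82 ± 0.21. Of 23 cytosolic ribosomal proteins 17 rose (19 adjusted over the list alone, 4.25e-08, adjusted p = 0.371 with an estimated correlation), RPL18 (LOC4334651) by 1.69 ± 0.27 and RPL27 by 1.32 ± 0.20. Photosynthesis had 7 of 8 genes higher and 1 lower (7 and 1 alone, 0.00348, adjusted p = 0.409 with an estimated correlation). The light-harvesting proteins LHCP (LOC4333359) changed by 2.28 ± 0.51 and CAB2R (LOC4324599) by 2.24 ± 0.40. Seed allergens and inhibitors had 2 of 3 higher (3 adjusted over the list alone, 0.0297, adjusted p = 0.371 with an estimated correlation). That call was also lost without unpollinated replicate 1 (adjusted p = 0.0555), without 4 DAP replicate 3 (0.0851), without the 3 arrays that stood apart (0.123) and with the 18S signal as a covariate (0.0517).

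The other 16 lists were not called in the bottom part at 4 DAP, though single members changed. In the sucrose list 6 of 24 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.660): the sugar carrier OsSWEET11 (LOC4346153) rose from 20.1 ± 4.21 to 78.9 ± 12.2 (log2 change 1.98 ± 0.24) and OsSWEET5 (LOC4339772) fell by 2.65 ± 0.20. Of 8 ovule and nucellus factors 2 rose and 1 fell (2 and 1 alone, 0.469), and the risers were OsMADS29 (LOC4328443), a MADS-box factor needed for nucellus breakdown, at 2.26 ± 0.33 and OsMADS21 (LOC4324888) at 1.90 ± 0.23. Embryo patterning factors had 4 of 18 higher and 5 lower (4 and 5 alone, 0.0528), with the KNOX homeobox genes OSH1 (LOC4333973) and OSH3 (LOC4333975) lower by -2.46 ± 0.25 and -2.27 ± 0.32. The hormone lists moved both ways: auxin 4 of 52 higher and 6 lower (4 and 6 alone, 0.730), gibberellin 4 of 9 and 2 (5 and 3 alone, 0.456), and cytokinin 2 of 21 and 3 (3 and 3 alone, 0.456). OsTAR2 (LOC4325198), of auxin synthesis, changed by 2.54 ± 0.59 and the auxin response factor OsARF8 (LOC4337363) by -2.53 ± 0.28. Without 4 DAP replicate 3 OsTAR2 changed by 3.46. OsCPS2 changed by 3.07 ± 0.61 (2.33 without 4 DAP replicate 1 and 4.06 without replicate 3), the gibberellin synthesis gene GA20OX3 (LOC4342505) by 2.67 ± 0.31, and the response regulators OsRRA14 (LOC4334066) and OsRRA19 (LOC4345758) by 2.98 ± 0.24 and 1.84 ± 0.26.

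Among the remaining lists of the bottom part at 4 DAP, cell wall loosening had 6 of 21 higher and 4 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.787). OsEXPB3 (LOC4349349) changed by 3.79 ± 0.96 (4.69 without 4 DAP replicate 3) and OsEXPA29 (LOC4342086) by -3.39 ± 0.35 (-2.80 without unpollinated replicate 1). These are genes of the list that was lower in replicate 3 at 3 and 4 DAP. Aquaporins had 4 of 19 higher and 4 lower (4 and 4 alone, 0.787). OsPIP1;3 (LOC4331194) changed by 2.98 ± 0.56 and OsTIP4;2 (LOC4324277) by -1.85 ± 0.29. Cellulose and callose synthesis had 4 of 22 and 1 (5 and 2 alone, 0.730). The cellulose synthase-like genes OsCslA1 (LOC4328585) and OsCslA9 (LOC4341571), in the list by symbol only, changed by 1.94 ± 0.26 and 1.02 ± 0.24. Defence proteins had 2 of 12 higher and 2 lower (3 and 2 alone, 0.987), including Cht1 (LOC4338719), a chitinase, at -2.21 ± 0.30 and OsChia4a (LOC4336265) at 0.73 ± 0.20. Polycomb and DNA methylation had 2 of 10 higher (3 alone, 0.569), DNA replication 1 of 26 (0 alone, 0.509), lipid transfer proteins 1 of 5 (2 alone, 0.413), endosperm transcription factors 1 of 3 (1 alone, 0.660) and seed storage proteins 0 of 3 (0 alone, 0.835). Heat shock proteins had 1 of 22 higher and 1 lower (0 and 1 alone, 0.660). For the auxin, cell wall and defence lists the median was above 0 (0.15, 0.13 and 0.29) while camera ranked the list below other genes. Over all probe sets 3518 rose and 2445 fell. OsChia4a lost its call without the 3 arrays that stood apart (adjusted p = 0.0660), without 4 DAP replicate 3 (0.0806) and without unpollinated replicate 1 (0.0767). With only the arrays compared in the fit it was lost too (0.0968), as were OsH2B (0.0681) and OsTAR2 (0.0532).

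**Figure D3:**
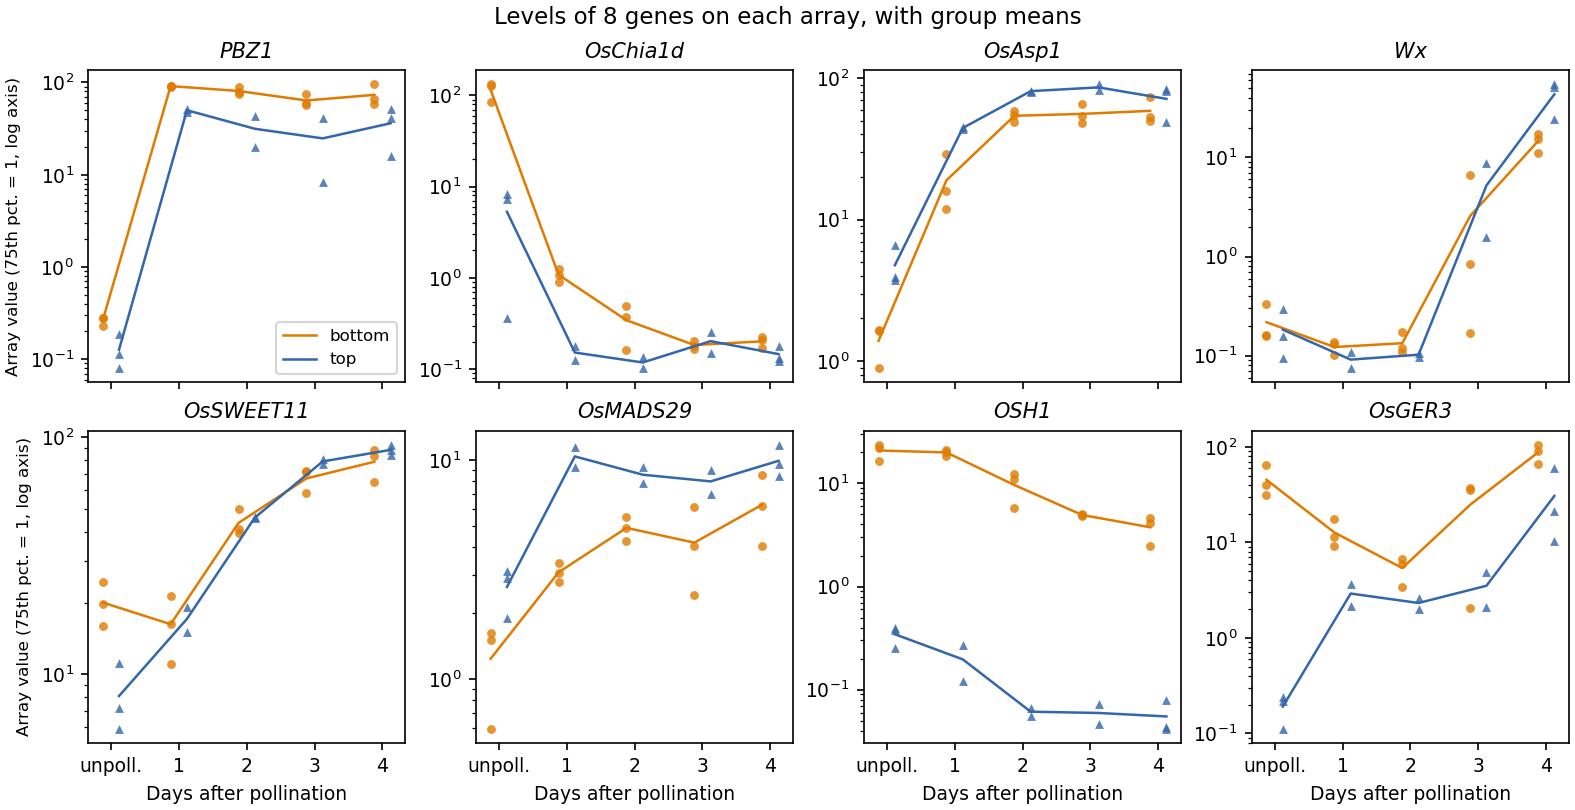
Value of 8 named genes on each array (points; log axis, relative to the array's 75th percentile) against the stage, with lines through the group means of the bottom and top part. PBZ1 goes from 0.264 to 91.4 in the bottom and from 0.127 to 50.1 in the top part between the unpollinated stage and 1 DAP, and Wx reaches 14.6 and 43.3 at 4 DAP.

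The same question was asked of the top part. PBZ1 rose 198-fold within 1 day, from 0.127 ± 0.0543 (SD, n = 3) to 50.1 ± 2.53 (SD, n = 2, limma log2 change 7.63 ± 0.48 SE, adjusted p = 2.28e-09), and CYP71Z7 rose 38.9-fold (5.28 ± 0.82). OsChia1d fell 11.2-fold at 1 DAP and 12.7-fold at 2 DAP, from a mean of 5.30 ± 4.30 (SD, n = 3), and was not called with only the arrays compared (adjusted p = 0.101 and 0.0838 in limma). The size of the OsChia1d fall rested on single unpollinated arrays, whose values were 8.24, 7.29 and 0.365. Its log2 changes of -3.48 and -3.66 at 1 and 2 DAP became -4.81 and -4.99 without unpollinated replicate 3, -2.77 and -2.95 without replicate 1, and -2.86 and -3.04 without replicate 2. OsMADS2 (LOC4325001), a floral organ MADS-box factor, fell 7.88-fold at 1 DAP and 10.7-fold at 3 DAP. At 2 DAP OsWRKY76 (LOC4347069), a WRKY transcription factor, rose 19.8-fold and PBZ1 116-fold, and OsCel9A (LOC4324643), an endoglucanase, fell 19.9-fold, followed by 21.1-fold at 3 DAP. PRX112 (LOC4344279), a peroxidase, rose 38.1-fold at 3 DAP, while PBZ1 was higher by 6.21 ± 0.48 with values of 8.45 and 41.1 on the 2 arrays. Without replicate 1 or 2 of 3 DAP that change of PBZ1 was 7.35 or 5.08, and that of PRX112 went from 5.25 to 5.99 with the 18S covariate.

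Mitosis genes and core histones also had the lowest camera adjusted p of the lists in the top part on the first day. All 6 core histones rose at 1 DAP (6 adjusted over the list alone, camera adjusted p = 2.52e-06, adjusted p = 0.198 with an estimated correlation), as did 11 of 14 mitosis genes, with 1 falling (12 and 1 alone, 1.28e-07, adjusted p = 0.198 with an estimated correlation), and 9 of 26 DNA replication genes (13 alone, 4.75e-04, adjusted p = 0.663 with an estimated correlation). Photosynthesis had 5 of 8 genes lower (5 adjusted over the list alone, 2.59e-05, adjusted p = 0.198 with an estimated correlation), with CAB2R at -2.38. Ribosomal proteins had 3 of 23 higher (6 alone, 0.0158, adjusted p = 0.765 with an estimated correlation), cell death proteases 2 of 3 (2 alone, 0.0289, adjusted p = 0.198 with an estimated correlation) and lipid transfer proteins 3 of 5 (3 alone, 0.0444, adjusted p = 0.406 with an estimated correlation). At 2 and 3 DAP 5 and 4 lists were called, none with an estimated correlation (lowest adjusted p = 0.372 and 0.515). Mitosis had 10 of 14 higher and 1 lower at 2 DAP (12 and 1 adjusted over the list alone, 3.00e-05), and photosynthesis had 7 of 8 higher at 3 DAP (7 and 1 alone, 0.0217). With quantile normalization the ribosomal, cell death and lipid transfer calls at 1, 2 and 3 DAP and the photosynthesis call at 3 DAP were lost (adjusted p up to 0.0995). The cell death calls were also lost with no filter (up to 0.288), with only the arrays compared at 1 and 2 DAP (0.0690 and 0.0522), and at 3 DAP with the 18S covariate (0.0555) or without 3 DAP replicate 2 (0.0568). That of ribosomal proteins at 1 DAP was lost without its replicate 2 (0.0978), and that of lipid transfer proteins at 1 DAP without either of its replicates (0.0541 and 0.0531) or unpollinated replicate 1 or 2 (0.0593 and 0.0778), with the replicate block (0.0575) and with only the arrays compared (0.0534). The 18S covariate also ended the photosynthesis call at 3 DAP (0.0555).

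In the top part 2884 probe sets rose and 2184 fell at 1 DAP, 3001 and 2424 at 2 DAP, and 4129 and 3266 at 3 DAP, with 2 arrays against 3 each. The 5068 calls at 1 DAP became 1883 without 1 DAP replicate 1 and 2528 without replicate 2, the 5425 at 2 DAP became 2297 and 2714 without its replicates 1 and 2, and the 7395 at 3 DAP became 2935 without its replicate 1, where each run left 1 array in the group. With quantile normalization the calls were 2704 higher and 2707 lower at 2 DAP and 3524 and 3757 at 3 DAP, so that the excess of rises was lost.

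Of the comparisons with the unpollinated stage, that of the top part at 4 DAP had the most probe sets called. Wx rose 135-fold, from 0.183 ± 0.104 to 43.3 ± 16.5 (SD, n = 3 each, log2 change 7.08 ± 0.70 SE, adjusted p = 1.71e-07), PBZ1 rose 128-fold (adjusted p = 2.26e-10), OsGER3 (LOC4344838), a germin-like protein, 75.6-fold (6.24 ± 0.75) with a mean of 30.7 ± 26.2, and PRX112 55.3-fold (5.79 ± 0.91). OsCel9A fell 28.2-fold (log2 change -4.82 ± 0.33, adjusted p = 1.19e-09). OsChia1d, FOR1 (LOC4343645), a leucine-rich repeat protein of floral organs, and OsTPP4 (LOC4330753), a trehalose phosphate phosphatase, fell 11.4-fold, 11.1-fold and 10.9-fold. Without 4 DAP replicate 1 or 3 the log2 change of OsGER3 was 6.84 or 5.57. That of OsChia1d, -3.51 in all arrays, was -2.80, -2.89 or -4.84 without unpollinated replicate 1, 2 or 3.

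In the top part 6 lists were called at 4 DAP, of which ribosomal proteins had the lowest camera adjusted p and seed allergens the largest median change, and all 6 calls were lost with an estimated correlation. All 3 seed allergens and inhibitors rose (3 adjusted over the list alone, camera adjusted p = 0.00822, adjusted p = 0.279 with an estimated correlation), RA5 (LOC4342727) by 3.36 ± 0.42 and RAG2 (LOC4342723) by 2.98 ± 0.45. Without 4 DAP replicate 3 these changes were 2.58 and 2.12. Starch synthesis had 6 of 9 genes higher and 1 lower (6 and 1 alone, 0.00822, adjusted p = 0.330 with an estimated correlation). SSII-3 changed by 5.02 ± 0.49 and AGPS2 by 3.22 ± 0.35. Lipid transfer proteins had 4 of 5 higher (5 adjusted over the list alone, 0.00822, adjusted p = 0.279 with an estimated correlation). LTP2-B (LOC4351317) changed by 4.59 ± 0.64 (5.34 without unpollinated replicate 3) and LTP110-A (LOC4349601) by 3.61 ± 0.41. Cell death proteases had all 3 higher (3 alone, 0.0354, adjusted p = 0.279 with an estimated correlation). OsAsp1 changed by 3.88 ± 0.30 and AP25 by 2.64 ± 0.52. Of 23 ribosomal proteins 19 rose (22 adjusted over the list alone, 2.70e-06, adjusted p = 0.406 with an estimated correlation), RPS26 (LOC4327570) 2.46-fold and RPL7A-2 (LOC4347522) by 1.18 ± 0.23. With quantile normalization the log2 changes were 0.78 for RPS26 and 0.66 for RPL7A-2, the latter not past the threshold (adjusted p = 0.0510). Photosynthesis had 6 of 8 higher and 1 lower (6 and 1 alone, 0.0413, adjusted p = 0.573 with an estimated correlation). LHCP changed by 2.41 ± 0.51 and PSAH (LOC4339593), a photosystem subunit, by 1.63 ± 0.24. The photosynthesis call was lost without unpollinated replicate 2 (adjusted p = 0.0706) or 3 (0.0556), without 4 DAP replicate 1 (0.0618) or 3 (0.0607), and with quantile normalization (0.0879), no filter (0.0530), the stricter filter (0.0861), the block (0.0588) and the 18S covariate (0.0685). The cell death call was lost with quantile normalization (0.0542), no filter (0.151), the stricter filter (0.0533) and only the arrays compared (0.0595), and the last also ended that of the seed allergens (0.0595).

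The sucrose list was not called in the top part (12 of 24 higher, 3 lower; 13 and 4 adjusted over the list alone, camera adjusted p = 0.110), though OsSUS3 rose by 4.52 ± 0.50 and OsSWEET11 by 3.48 ± 0.24, from 8.08 ± 2.73 to 88.6 ± 4.23. Mitosis had 7 of 14 higher and 1 lower (11 and 1 alone, 0.104). CycB2;2 changed by 1.87 ± 0.42 and CYCB1-3 (LOC4326914) by 1.39 ± 0.29. Core histones had 2 of 6 higher (2 alone, 0.195). DNA replication had 3 of 26 lower (1 adjusted over the list alone, 0.195). OsRPA32C (LOC9266781), a subunit of replication protein A, changed by -1.20 ± 0.18 and OspolD1 (LOC4349968), of DNA polymerase delta, by -0.76 ± 0.28. OspolD1 lost its call without unpollinated replicate 2 (adjusted p = 0.187), without 4 DAP replicate 1 (0.0886) or 3 (0.128) and with no filter (0.0579). Cell wall loosening had 9 of 21 higher and 2 lower (10 and 2 alone, 0.2). OsEXPB3 changed by 4.99 ± 0.96 and OsEXPB6 (LOC4349347) by 3.59 ± 0.71. Aquaporins had 8 of 19 and 2 (9 and 2 alone, 0.195). OsPIP1;3 changed by 2.97 ± 0.56 and OsPIP2;7 (LOC4347729) by 2.94 ± 0.33. Of the ovule and nucellus factors 3 of 8 rose (3 alone, 0.675), OsMADS29 by 1.88 ± 0.33 and OsMADS21 by 0.91 ± 0.23. Embryo patterning factors had 3 of 18 higher and 5 lower (3 and 5 alone, 0.139). OSH45 (LOC4345191) changed by -1.87 ± 0.26 and OSH1 by -1.35 ± 0.25.

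Hormone genes of the top part at 4 DAP moved both ways: 14 of 52 auxin genes rose and 11 fell (14 and 11 adjusted over the list alone, camera adjusted p = 0.904). The auxin response repressors IAA13 (LOC4334069) changed by 3.19 ± 0.36 and IAA14 (LOC4334431) by 2.90 ± 0.54. Gibberellin had 3 of 9 higher and 1 lower (3 and 1 alone, 0.495). GA20OX3 changed by 2.47 ± 0.31 and CYP714D1 (LOC4339131), which inactivates gibberellins, by 2.39 ± 0.18. Cytokinin had 3 of 21 and 5 (4 and 6 alone, 0.139). OsRRA19 changed by 2.73 ± 0.26 and the cytokinin oxidase OsCKX11 (LOC4345764) by -1.79 ± 0.51. Polycomb and DNA methylation had 2 of 10 higher and 2 lower (2 and 2 alone, 0.811). The DNA methyltransferase OsMET1b (LOC4342575) changed by 1.79 ± 0.33 and the DNA glycosylase DNG701 (LOC4338940) by -1.12 ± 0.28. Camera ranked this list below other genes although its median was 0.04. Cellulose and callose synthesis had 6 of 22 and 2 (8 and 3 alone, 0.452). The cellulose synthase-like gene OsCslA1 changed by 1.88 ± 0.26 and OsCesA8 (LOC4342699) by 1.44 ± 0.29. Heat shock proteins had 1 of 22 and 2 (1 and 1 alone, 0.575). OsHsp17.4 (LOC4332360) changed by 3.11 ± 0.69 and OsHsp17.9B (LOC4325695) by -2.20 ± 0.41. Defence proteins had 1 of 12 and 2 (1 and 2 alone, 0.904), with Cht11 (LOC4331519) at -2.80 ± 0.46. Endosperm transcription factors had 1 of 3 higher (1 alone, 0.452) and seed storage proteins 1 of 3 (1 alone, 0.940), the glutelin gene GLUB-5 (LOC4328968) at 2.02. Over all probe sets 5307 rose and 4837 fell, but 4707 and 5044 with quantile normalization and 4996 and 5272 with no filter.

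**Figure D4:**
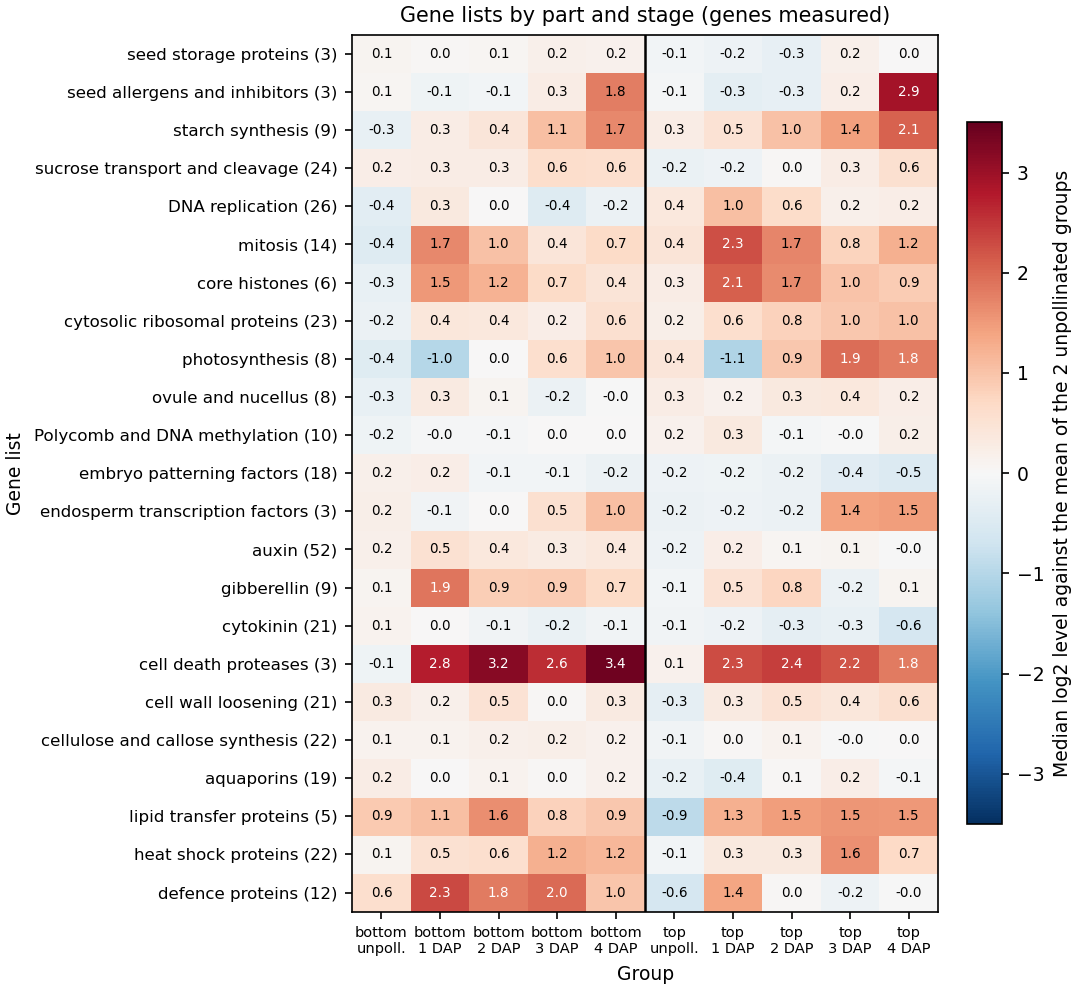
Median log2 level of each of 23 gene lists (vertical axis, with the number of genes measured) in each of the 10 groups (horizontal axis), relative to the mean of the 2 unpollinated groups; colour runs from -3.5 to 3.5. Starch synthesis and the seed allergens are highest at 4 DAP, and core histones are highest at 1 and 2 DAP.

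Changes of the parts, measured on separate arrays, overlapped. At 1 DAP 1521 probe sets were called higher in both parts, where independent lists of these sizes would share 225, and 775 lower in both (122 for independent lists), while 22 were called in opposite directions (332). At 4 DAP 2775 were higher in both (637), 1411 lower in both (403) and 98 opposite (1023), and log2 changes of the parts correlated over probe sets with r = 0.733 at 1 DAP and 0.702 at 4 DAP. Probe sets are not independent replicates. Both parts were also tested with 1 pooled spread per probe set, so probe sets of low spread can be called in both. This can raise shared calls in the same and in opposite directions, so the numbers for independent lists are only a rough reference.

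How the parts differed was asked at each stage. Before pollination the KNOX gene OSH1 stood at 20.9 ± 3.69 in the bottom and 0.345 ± 0.0804 in the top part (SD, n = 3 each), 44.2-fold lower in the top (log2 difference -5.46 ± 0.25 SE, adjusted p = 9.92e-12), and OsGER3 was 137-fold lower in the top. OsRRA14 and OsHAK1 (LOC4335729), a potassium transporter, were 4.21-fold and 4.17-fold higher in the top part. OSH1 stayed lower in the top part after pollination, by -5.98 ± 0.28 at 1 DAP, -5.61 ± 0.28 at 2 DAP and -4.75 ± 0.28 at 3 DAP. OsMT-I-2b (LOC4326409), a metallothionein, was 66.1-fold lower in the top at 1 DAP, OsMADS16 (LOC4342047), a floral organ MADS-box factor, 14.2-fold lower at 2 DAP, and ML (LOC4326471) 34.9-fold lower at 3 DAP. Higher in the top part were PCF8 (LOC4352799), a TCP transcription factor, 4.77-fold at 1 DAP and 2.55-fold at 2 DAP, OsNramp5 (LOC4342859), a manganese transporter, 4.05-fold, 4.67-fold and 5.49-fold at 1, 2 and 3 DAP, and OsrbcS (LOC4351966), the Rubisco small subunit, 4.96-fold at 3 DAP.

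Lists that differed between the parts before pollination numbered 13, and those at 1, 2 and 3 DAP 9, 11 and 7. Before pollination DNA replication genes were higher in the top part, 12 of 26 (21 adjusted over the list alone, camera adjusted p = 1.26e-06, adjusted p = 0.350 with an estimated correlation), and aquaporins lower, 8 of 19 (8 alone, 0.00120, adjusted p = 0.206 with an estimated correlation). In the embryo patterning list 3 of 18 genes were higher and 8 lower in the top before pollination (5 and 8 alone, 0.0119, adjusted p = 0.206 with an estimated correlation), a call also lost with no filter (0.0546) and the stricter filter (0.120). At 1 DAP embryo patterning factors, with 3 higher and 7 lower (4 and 8 adjusted over the list alone, 1.28e-04), and gibberellin, with 2 of 9 lower (2 alone, 0.00130), were the 2 lists of any comparison whose calls held with an estimated correlation (adjusted p = 0.0355 and adjusted p = 0.0348). Defence proteins ranked lower in the top at 2 DAP (camera adjusted p = 1.21e-05, adjusted p = 0.0547 with an estimated correlation) with 0 of 12 called and 4 lower adjusted over the list alone. At 3 DAP 15 of 23 ribosomal proteins were higher in the top (20 alone, 2.07e-12, adjusted p = 0.161 with an estimated correlation).

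Between the parts 2006 probe sets were higher and 2385 lower in the top before pollination, 386 and 805 at 1 DAP, 108 and 328 at 2 DAP, and 1111 and 461 at 3 DAP. Before pollination the split depended on the setting, with 360 higher and 1535 lower at a minimum change of 2-fold. It was 2847 and 2460 with quantile normalization, 2855 and 2834 with the replicate block, and 2561 and 2477 without top replicate 3. At 3 DAP it turned to 98 higher and 141 lower with the block by stage, 0 and 19 with only the arrays compared, and 21 and 49 without top replicate 1. These counts rested on few arrays: the 4391 before pollination became 2415 without bottom replicate 3 and 2482 without top replicate 2, the 1191 at 1 DAP 384 and 597 without top replicates 1 and 2, and the 436 at 2 DAP 245 without bottom replicate 1 and 143 and 130 without top replicates 1 and 2. The 1572 at 3 DAP became 3530, 1044 and 541 without bottom replicates 1, 2 and 3, and 70 without top replicate 1. In that comparison, without top replicate 1 ML (adjusted p = 0.220), OsNramp5 (0.107) and OsrbcS (0.0727) lost their calls. They also lost them with the replicate block by stage (0.110, 0.0774 and 0.0509) and with only the arrays compared (0.258, 0.207 and 0.350), and ML lost its call without top replicate 2 (0.0893) or bottom replicate 3 (0.131). The log2 difference of ML, -5.12 in all arrays, was -4.17 without bottom replicate 3, the value also given by the block by stage, -5.94 without bottom replicate 1, -4.45 with the replicate block and -6.11 with the 18S covariate. At 1 DAP OsNramp5 lost its call without bottom replicate 1 or either top replicate (up to 0.157), at 2 DAP without bottom replicate 3 or either top replicate (up to 0.251), with the block by stage (0.156) and with only the arrays compared (0.140), and PCF8 at 2 DAP without either top replicate (up to 0.177).

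At 4 DAP OSH1 was 20.5-fold lower in the top part, 0.0551 ± 0.0214 against 3.76 ± 1.12 (SD, n = 3 each, log2 difference -4.35 ± 0.25 SE, adjusted p = 2.59e-09), OsMADS16 9.86-fold lower, the KNOX gene OSH71 (LOC4337701) 9.12-fold lower and CYP71Z7 8.11-fold lower. OsNramp5 was 6.36-fold higher in the top (2.67 ± 0.41, adjusted p = 7.98e-04), SSII-3 4.10-fold (2.04 ± 0.49), OsrbcS 3.08-fold (1.62 ± 0.33) and OsPPDKB (LOC4338750), a pyruvate phosphate dikinase of endosperm, 2.95-fold (1.56 ± 0.38). In total 374 probe sets were higher and 377 lower in the top, and 139 and 257 at a minimum change of 2-fold. Leaving out bottom replicate 1, 2 or 3 gave 420, 334 or 500 calls and leaving out top replicate 2 or 3 gave 332 or 331, against 751. SSII-3 and OsPPDKB lost their calls in 4 of these runs, without bottom replicate 1 or 2 or top replicate 2 or 3 (adjusted p up to 0.160 and 0.192), OsrbcS without bottom replicate 1 or top replicate 1 or 3 (up to 0.0579), and CYP71Z7 without any of the arrays except bottom replicate 3 (up to 0.128). All 4 genes were also not called with only the arrays compared (0.0680, 0.129, 0.103 and 0.212), and CYP71Z7 was not called with the block by stage (0.0515) and quantile normalization (0.0631). The log2 difference of CYP71Z7, -3.02 in all arrays, was -2.08 without bottom replicate 1 and -4.26 without bottom replicate 3.

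The embryo patterning list was lower in the top part at 4 DAP, with 4 of 18 genes called (6 adjusted over the list alone, camera adjusted p = 2.14e-04, adjusted p = 0.0780 with an estimated correlation), OSH45 at -1.42 ± 0.26 and OSH6 (LOC4325788) at -0.81 ± 0.21. OSH6 was not called under 11 alternatives, among them leaving out bottom replicate 2 or 3 (adjusted p = 0.180 and 0.138) or top replicate 1, 2 or 3 (up to 0.164), and OSH45 was not called with only the arrays compared (0.143). Defence proteins had 1 of 12 lower (2 alone, 0.00682), auxin 1 of 52 (1 alone, 9.35e-04) and gibberellin 2 of 9 (3 alone, 0.0449), each with adjusted p = 0.210 with an estimated correlation. Higher as a set in the top were ribosomal proteins, 1 of 23 (17 adjusted over the list alone, 4.06e-09), starch synthesis, 1 of 9 (3 alone, 0.00305), and seed allergens, 0 of 3 (2 alone, 0.0136), each with adjusted p = 0.210 with an estimated correlation. Mitosis (0 of 14, then 0 alone, 0.00139) and photosynthesis (1 of 8, then 2 alone, 0.00384) ranked higher with adjusted p = 0.299 with an estimated correlation, and DNA replication (0 of 26, then 0 alone, 0.00384) with adjusted p = 0.527. Cytokinin ranked lower (0 of 21, then 1 higher and 1 lower alone, 0.0419, adjusted p = 0.210 with an estimated correlation). The gibberellin call ended under 10 alternatives, among them leaving out bottom replicate 1 or 2 (adjusted p = 0.0617 and 0.0666) or top replicate 1 or 2 (0.160 and 0.0702). The cytokinin call ended under 9, among them leaving out bottom replicate 1 or 2 (0.0639 and 0.123) or top replicate 2 or 3 (0.0562 and 0.0614). That of the seed allergens ended without bottom replicate 1 or top replicate 3 (0.0823 and 0.0614) and with only the arrays compared (0.110), that of defence proteins without top replicate 1 (0.0797), and that of DNA replication with the stricter filter (0.0705).

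Whether the parts changed unequally since the unpollinated stage was tested directly as a difference of changes. At 4 DAP the difference was 5.28 ± 0.81 for OsRAA1 (SE, adjusted p = 5.24e-04), 5.25 ± 1.07 for OsGER3, 4.90 ± 0.88 for OsChia1d and 3.27 ± 0.51 for IAA13. The levels before pollination were unequal, which enters these differences. OsRAA1 went from 21.8 to 0.398 in the bottom part and from 0.476 to 0.420 in the top, where a fall as large as in the bottom was not possible above the pseudocount of 0.13, and OsChia1d went from 114.8 to 0.201 and from 5.30 to 0.146. OsGER3 went from 45.3 to 87.6 in the bottom and from 0.191 to 30.7 in the top, and IAA13 from 29.02 to 27.68 and from 2.51 to 21.4. OsRRA14 rose more in the bottom part (difference -1.97 ± 0.34), and OsGLU8 (LOC4327286) differed by -2.75 ± 0.40. Without top 4 DAP replicate 1 or 3 the difference of OsGER3 was 5.85 or 4.58. Of the sugar carriers OsSWEET11 differed by 1.51 ± 0.33 and OsSWEET5 by 1.49 ± 0.28. In total 307 probe sets were called at 1 DAP (223 higher in the top), 446 at 2 DAP (364), 1177 at 3 DAP (929) and 1083 at 4 DAP (802). Each of these counts uses the same unpollinated arrays. The unequal levels before pollination, with 360 probe sets higher and 1535 lower in the top at 2-fold, enter these counts and the lists below too. Lists called at 4 DAP were lipid transfer proteins (1 of 5 higher in the top, 4 adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.472 with an estimated correlation), cell wall loosening (5 of 21, then 5 alone, 0.0187, adjusted p = 0.756 with an estimated correlation), aquaporins (3 of 19, then 5 alone, 0.0337, adjusted p = 0.539 with an estimated correlation) and, lower in the top, DNA replication (0 of 26, then 0 alone, 0.00746, adjusted p = 0.855 with an estimated correlation). The cell wall call was lost without bottom 4 DAP replicate 3 (0.126) and without the 3 arrays that stood apart (0.219), as well as with the stricter filter (0.120) and only the arrays compared (0.0519). The aquaporin call ended under 9 alternatives, among them leaving out unpollinated bottom replicate 3 (0.0596) or top replicate 2 (0.165), 4 DAP bottom replicate 1 (0.0968) or 4 DAP top replicate 1 or 3 (0.0513 and 0.0533). That of DNA replication ended without bottom unpollinated replicate 3 (0.117) or top unpollinated replicate 2 (0.167).

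The counts of unequal change also moved with single arrays. That at 4 DAP became 683 without bottom unpollinated replicate 3, 693 without top unpollinated replicate 2 and 642 without top 4 DAP replicate 3. Those at 1 and 2 DAP became 122 and 130, and 229 and 229, without replicates 1 and 2 of the top group of that day, and that at 3 DAP 1782 without bottom 3 DAP replicate 1 and 354 without top 3 DAP replicate 1.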

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

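All tests named here were chosen before their results were seen, except the 3 tests on the bottom arrays that stood apart and the test on the spread of the 4 DAP arrays, which were chosen only after those patterns had been seen.

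The values here and in the next paragraph are listed because the change since the unpollinated stage differed between the parts in a direct test. Probe sets with an unequal change numbered 307 at 1 DAP, 446 at 2 DAP, 1177 at 3 DAP and 1083 at 4 DAP. At 4 DAP the median differences of the lists called were -0.40 for DNA replication, 0.63 for cell wall loosening, 0.32 for aquaporins and 1.88 for lipid transfer proteins. Levels relative to the mean of the 2 unpollinated groups were unequal before pollination. Median log2 levels of lipid transfer proteins were 0.90 (bottom) and -0.90 (top), then 0.94 and 1.52 at 4 DAP. Those of cell wall loosening were 0.32 and -0.32, then 0.32 and 0.56. DNA replication had -0.38 and 0.38, then -0.21 and 0.24, and aquaporins 0.25 and -0.25, then 0.15 and -0.07. This unequal start enters the differences, which are not read as unequal regulation. Genes that differed at 1 DAP were OsGER3 (5.03), OsGLU15 (LOC4345463, 4.12), OsOPR5 (LOC4340485, -3.32), an oxophytodienoate reductase, and OsABCG45 (LOC4346210, -2.86), an ABC transporter. The call of OsGER3 at 1 DAP was lost under 9 settings, 8 of them runs without 1 array (adjusted p = 0.1999 without top 1 DAP replicate 1). At 2 DAP they were OsGER3 (5.97), OsChia1d (4.30), the cystatin OC-VI (LOC4332021, -2.42) and the glutamine synthetase OsGLN1;2 (LOC4332108, -2.30). At 2 DAP OC-VI lost its call under 11 settings (up to 0.203 with the block by stage), OsChia1d under 6 (up to 0.241 with only the arrays compared) and OsGLN1;2 without top 2 DAP replicate 2 (0.104). At 3 DAP they were OsMT-I-2b (5.29), OsChia1d (5.24), OsHAK1 (-2.29) and the ammonium transporter OsAMT1 (LOC4336365, -2.16). Of these OsAMT1 lost its call under 10 settings (up to 0.284) and OsHAK1 under 5 (up to 0.217), the highest in both without top 3 DAP replicate 1, and OsChia1d with only the arrays compared (0.0997). Without top unpollinated replicate 3 the differences of OsChia1d were 2.97 at 2 DAP and 3.91 at 3 DAP, without replicate 1 5.01 and 5.95, and without replicate 2 4.93 and 5.86.

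The genes named by rule for the difference at 4 DAP were OsRAA1 (5.28), OsGER3 (5.25), OsGLU8 (-2.75) and OsRRA14 (-1.97). Genes named in other comparisons that differed between the parts were OsChia1d (4.90), IAA13 (3.27), OsEXPA29 (2.99), OsEXPB9 (2.40), OsTIP4;2 (2.33), Cht1 (1.86), OSH3 (1.83), OsSWEET11 (1.51) and OsSWEET5 (1.49), with the top part higher. OsCel9A (-1.85), OSH45 (-1.83) and OsTPP4 (-1.58) differed the other way. OsRAA1, OsChia1d, OsEXPB9 and OsEXPA29 started higher in the bottom part (21.8, 114.8, 8.90 and 4.52 against 0.476, 5.30, 1.42 and 0.328) and were not called between the parts at 4 DAP (log2 difference -0.02, -0.27, -0.26 and -0.14). Their differences of change thus came mainly from the unequal levels before pollination and are not read as unequal regulation. IAA13 and OsSWEET11 also started higher in the bottom part and lay closer together at 4 DAP, so the same limit holds for them. A control probe outside the main measurement also stood out, the 18S ribosomal RNA of bottom 4 DAP replicate 3 at 33.6, above the highest unpollinated array at 12.8.

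The number of unequal changes at 4 DAP was reached by 18 of 100 relabellings of arrays within each part, the real one included, and the highest other count was 7222. All 17 others left the day effect unequal in the 2 parts, and the 35 relabellings that kept it equal had at most 0 called. The test therefore measures the structure of the samples and does not tell a real difference from a mixed one. For the comparisons of 3 with 3 arrays, 1 of 10 splits had as many called, the real one, and 10 splits are too few for a share under 0.05. The highest other counts were 2, 2, 26 and 5 for the bottom part at 1 to 4 DAP against 3931, 4177, 4692 and 5963, and 0 for the top part at 4 DAP against 10144. Between the parts they were 654 before pollination against 4391 and 0 at 4 DAP against 751.

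Bottom replicates 3 of 3 and 4 DAP stood apart from their groups, and replicate 3 of 2 DAP was tested with them. At 2 DAP replicate 2 deviated from the group mean about as far as replicate 3 (root mean square log2 deviation 0.356 and 0.367). Of the 3, 1 had a 3-prime to 5-prime control ratio above the highest of the other 12 bottom arrays (GAPDH 2.14 against 2.09, at 3 DAP). This argues against more RNA degradation than in those 12 arrays only for replicates 3 of 2 and 4 DAP. Actin ratios of the other 12 ran from 6.15 to 15.1, and the test cannot tell whether RNA was degraded on the bottom arrays in general. Top arrays under a bottom label are argued against for these 3 by 0 of 3 correlating best with a top array. Bottom 2 DAP replicate 2, which was not tested, did correlate best with one (top 2 DAP replicate 1, r = 0.965). The highest r within its own group was 0.961. Stress before the RNA was taken could account for 4 DAP replicate 3, as the pooled median deviation of the heat shock list (0.66) lay at percentile 100 of 10000 random lists, but that value rested mainly on this array (1.35). For the arrays at 2 and 3 DAP, with 0.30 and 0.24, it stays open. The random lists were matched on mean expression only, so the percentile does not allow for genes that vary together. Other lists deviated further, lipid transfer proteins by -0.76 and cell wall loosening by -0.72. The test therefore cannot single out stress, which stays open for 4 DAP replicate 3 too. A biological difference by design of collection stays open as untested.

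Between the parts more probe sets differed before pollination (4391) than at 4 DAP (751). Whether a wide spread of the 4 DAP arrays lowered that count cannot be decided. Without the 3 arrays that stood apart 845 were called at 4 DAP and 6135 before pollination. The fit pools the spread of all groups, with a median SE of 0.214 in both comparisons. A wide spread at 4 DAP would thus widen the SE of both, and the run left fewer bottom arrays at 4 DAP. Unequal ribosomal RNA in the label is argued against, because with the 18S covariate 4627 were called before pollination and 707 at 4 DAP. That the parts differ in tissue before pollination by the way they were divided stays open as untested.

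PBZ1 rose over 100-fold at 1 DAP in both parts. RNA of the blast fungus is argued against by 0 of 2 parts with higher control probes of that fungus at 1 DAP (mean differences -0.0634 and -0.0699). A general rise of defence genes cannot be told, since the defence list was called in 1 of 2 parts and only with the preset correlation (adjusted p = 0.357 with an estimated one). Its median log2 level, relative to the mean of the 2 unpollinated groups, was higher at 1 DAP in both parts. It went from 0.58 to 2.31 in the bottom and from -0.58 to 1.39 in the top. The missing call in the top part is therefore not read as no rise. Of the 3 bottom arrays that stood apart, 1 had the highest PBZ1 of its group. These arrays were of 2, 3 and 4 DAP, when PBZ1 lay between 57.0 and 95.3 on all bottom arrays. This test therefore cannot decide whether stress raised PBZ1 at 1 DAP, and stress was not established in these arrays. A response to pollination itself stays open as untested.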

How the results depend on the processing

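Numbers are probe sets called, in the order of the comparisons in the report. Quantile normalization, arrays shifted to 1 median, both other pseudocounts and no intensity trend left all 17 counts within 1.5-fold, and no named gene or called list turned direction. The majority of calls did turn with quantile normalization, from 55.32% to 49.97% higher in the top part at 2 DAP, 55.84% to 48.4% at 3 DAP, 52.32% to 48.27% at 4 DAP, and 45.68% to 53.65% between the parts before pollination. At 4 DAP between the parts the near-even split also turned under several settings. A minimum change of 2-fold gave 1928, 2038, 2190 and 2779 in the bottom part, 2558, 2598, 3536 and 4520 in the top part, and 1895 before pollination (360 higher, 1535 lower), 792 at 3 DAP and 396 at 4 DAP between the parts. The filter at the 75th percentile, which tests fewer probe sets, gave 2494, 2624, 2943 and 3914 in the bottom part and 3300, 3594, 4852 and 6207 in the top part. Between the parts it gave 2766 before pollination, 554 at 1 DAP, 203 at 2 DAP and 378 at 4 DAP, and 76, 183, 674 and 534 for the difference of changes. No filter gave 937 between the parts at 3 DAP. The replicate block gave 1155 between the parts at 4 DAP, and the block by stage 265 at 2 DAP and 239 at 3 DAP, and 166, 244 and 547 for the difference at 1 to 3 DAP. Only the arrays of the groups compared gave 2509, 1304 and 3201 in the bottom part at 2 to 4 DAP and 2973, 2738 and 3857 in the top part at 1 to 3 DAP. Between the parts it gave 1916 before pollination and 188, 19 and 110 at 2 to 4 DAP, and 163, 169, 208 and 651 for the difference. Of the alternatives chosen after the data had been seen, the 18S covariate gave 2440 between the parts at 3 DAP. Omitting the 3 bottom arrays that stood apart gave 1947 at 1 DAP and 717 at 3 DAP between the parts, and 532 at 1 DAP and 1625 at 4 DAP for the difference. The cause of these shifts was not tested.

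Leaving out 1 array at a time gave 2590 to 3275, 2747 to 3816, 3403 to 4199 and 4266 to 5616 in the bottom part at 1 to 4 DAP, and 1883 to 4750, 2297 to 5108, 2935 to 7023 and 8154 to 9712 in the top part. Between the parts it gave 2415 to 5038 before pollination and 384 to 880, 130 to 437, 70 to 3530 and 331 to 534 at 1 to 4 DAP. The difference gave 122 to 360, 229 to 553, 354 to 1782 and 642 to 1297. The arrays that moved a count by over 1.5-fold are named with their counts in the report. A run that leaves 1 array in a top group assumes that this array varies like the other groups. Of 153 named gene results 26 were lost under some setting. Of 116 list results called, 114 were lost under some setting and 59 under one other than the estimated correlation, including list calls outside 4 DAP that were run only after the data had been seen. Quantile normalization moved the share of probe sets called higher by at most 7.97 points. Pairing of the parts by replicate number was not seen. Of 12 pairs with the same number, 3 had deviations correlated over 0.1 (r from -0.634 to 0.315). These pairs are not independent, since in top groups of 2 arrays the deviations of the arrays mirror each other. Among pairs with different numbers r reached 0.560 before pollination and 0.634 at 2 DAP, with others down to -0.566 and -0.558. At 4 DAP it was at most 0.218. Whether arrays of the parts share ovaries or a batch under other numbers was not tested, and the tests between the parts use no such pairing.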

Other observations

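Further genes of sugar supply, picked after their values had been seen, changed at 4 DAP (n = 3 in each group, limma). The sucrose transporter OsSUT1 (LOC4331775) rose in the top part by 2.04 ± 0.35 SE (adjusted p = 1.34e-04) but not in the bottom part (-0.26 ± 0.35, adjusted p = 0.692), and the changes differed by 2.30 ± 0.50 (adjusted p = 0.0103). The cell wall invertase GIF1 (LOC4335790) rose in both parts, by 1.27 ± 0.34 in the bottom and 2.48 ± 0.34 in the top, as did the sugar carrier OsSWEET15 (LOC4329464), by 1.27 ± 0.29 and 1.75 ± 0.29. The sucrose synthase OsSUS4 (LOC4332788) rose in the top part by 1.26 ± 0.21. Of regulators, OsNF-YB-1 (LOC4330587), an endosperm factor, rose by 1.56 ± 0.25 and 2.52 ± 0.25, and OsVP1 (LOC4324314), a B3 factor of seed maturation, by 1.18 ± 0.21 and 1.19 ± 0.21, while OsMADS6 (LOC4330328) fell in the bottom part (-1.16 ± 0.26).

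Variation within groups lay to 42.9% on 1 axis, highest on the bottom arrays that stood apart. Per standard deviation of arrays along it, the protein kinase gene CPDK2 (LOC4333181) changed by 1.78, the chitinase gene Chib3H-a (LOC4351194) by 1.67 and the amylase gene AMY1.3 (LOC4345814) by 1.37. The calmodulin-like CML10 (LOC4325762) changed by -1.01, OsEXPB3 by -0.87 and the trehalose phosphate phosphatase OsTPP7 (LOC4346885) by -0.79.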
